A study of Mus musculus with 4 samples.

How the data were processed

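Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on kidney tubular cells from newborn mice, in which the immunoprecipitated DNA is sequenced beside an input library of unselected chromatin. There were 4 libraries, a ChIP and an input from littermate controls and a ChIP and an input from Foxp1KspKO mice, and each group held 1 library. Per the labels' protocols, kidneys were digested with collagenase, passed through a sieve, and the sheared chromatin was incubated with a Foxp1 polyclonal antibody or with rabbit IgG. The antibody field of the labels names rabbit IgG for the control ChIP and the Foxp1 antibody for the Foxp1KspKO ChIP, while the sample descriptions and the deposited lists give both libraries the same FoxP1 prefix. The field was not altered or resolved, and the libraries are named here by the genotype in their titles.

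The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, deepTools and edgeR and the mouse builds GRCm38 and mm10, with no version and no role for each. The authors deposited 3 lists of genes. Each list gives a gene symbol, an NCBI gene number, an Ensembl gene identifier and 1 p-value per gene as the authors computed it, and the deposited values lie under 0.05. The lists carry no peak position, fold enrichment, read count or direction. The test behind the p-values, its reference library, the region around a gene that was tested and any correction for multiple testing are not given in the sources used here. Read depth is therefore unknown and no interval on the ChIP signal can be given. Many genes share exactly the same p-value (67.2% of the control genes and 61.0% of the Foxp1KspKO genes), so ranks within ties are arbitrary.

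The first list was taken for the control ChIP and the second for the Foxp1KspKO ChIP because their sheet names match the sample descriptions, and the third is the authors' list of genes unique to the control ChIP. Rows were joined by NCBI gene number, with the lowest p-value kept where a number occurred more than once. In the RefSeq gene table for GRCm38.p6, 2 of the 6799 control genes and 1 of the 4953 Foxp1KspKO genes had no entry. Gene coordinates come from that table, are 1-based, and describe the gene, not a binding site. Some symbols in the lists differ from the symbol of the same number in the table. The symbol in the list was then printed, and membership in a fixed gene list followed the number.

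The planned comparisons assumed peak positions, and the lists hold genes. Overlap was therefore counted by gene, peak strength was taken as −log10 of the deposited p-value, and the planned annotation of peaks to promoters and the forkhead motif search were not run. Overlap between the control and Foxp1KspKO lists was set against 1000 random draws that took the same number of protein-coding genes from each chromosome (one-sided permutation p). Strength was compared between control genes with and without a Foxp1KspKO listing by a two-sided permutation test of the difference in medians with 100000 resamples. A total of 15 gene lists with 348 distinct genes, all found in the table, were fixed before the data were examined. They cover the cell types of the nephron and its surroundings, the Notch and Wnt pathways, kidney developmental regulators, the forkhead family, V-ATPase subunits, the cell cycle and ribosomal proteins as a comparison. Each was tested among the unique control genes by a two-sided Fisher's exact test against all 21900 protein-coding genes, with Benjamini-Hochberg adjustment over the 15 lists. Genes are not replicates, and these tests describe the deposited lists of 1 library per genotype, not the genotypes. Differences between the libraries were tested on genes present in only 1 of the 2 lists, by Fisher's exact test, over a family of 16 comparisons. The family holds the 15 fixed lists and X against autosomes, which was added after the data were seen. Intervals are exact Clopper-Pearson 95% intervals for shares and conditional 95% intervals for odds ratios, and cover counting error only.

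Genes named in the text follow a rule fixed before the data were examined: the 10 unique control genes with the lowest p-value, the 5 lowest in the Foxp1KspKO list, the 5 lowest control p-values among shared genes, up to 8 unique genes of the intercalated cell, Notch, forkhead and V-ATPase lists, up to 3 of each other list, and Foxp1 and Cdh16. A gene that this rule names is not reported here. The counts of list members that pass an adjustment treat the deposited p-values as unadjusted and give unlisted genes the highest possible value.

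On simulated lists drawn from the 21900 genes with 3302 hits, Fisher's exact test gave p under 0.05 for 1.50% of unrelated lists of 20 genes and 2.50% of those of 30 genes. It found 63.5% and 79.0% of lists with a true odds ratio of 3, and 95.0% and 99.0% with an odds ratio of 6. These rates are for unadjusted p-values and for hits and members drawn at random from all genes. They do not cover lists that lean towards long or related genes. The calls on the fixed lists use adjusted p-values, so fewer true excesses would be found. The smallest fixed list has 16 members, a size that was not simulated. The overlap test gave p under 0.05 for 3.00% of pairs of unrelated lists, drawn by the same random scheme as the test. A low rate follows from that scheme. It does not show how the test behaves on lists that share gene length or background. Of the alternatives tried, 7 were added after the data were seen. The alternatives were a stricter p-value limit, autosomes only, draws matched on gene length, other definitions of control-only genes, gene symbol families left out and an adjustment over all genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.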

Results

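To search for genes that the forkhead transcription factor Foxp1 may bind directly in the distal tubule, the study compared ChIP-seq of newborn kidney tubular cells from littermate controls with that from Foxp1KspKO mice, 1 ChIP and 1 input library each. The name of the knockout refers to Ksp-cadherin, the product of Cdh16, whose promoter is used to drive Cre recombinase in renal tubule epithelium. The data are lists of genes with p-values, and the number of reads behind them is unknown. With 1 library per genotype, a difference between the lists has no replicate check. The antibody field of the labels assigns rabbit IgG to the control ChIP and the Foxp1 antibody to the Foxp1KspKO ChIP, so the direction of each comparison rests on the genotype in the titles and not on a settled antibody.

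The control ChIP had the longer list, with 6799 genes against 4953 for the Foxp1KspKO ChIP, and the stronger one. A p-value under 1e-10 in the authors' deposited table was listed for 508 control genes (7.47%) and 57 Foxp1KspKO genes (1.15%), and the median p-values were 0.00116 and 0.00533. Protein-coding genes made up 93.3% and 92.3% of the lists, which is 29.0% and 20.9% of all protein-coding genes. Long noncoding RNA genes numbered 299 and 245, and microRNA genes 96 and 82. Neither Foxp1 itself (chromosome 6, 98925342 to 99522746, GRCm38) nor Cdh16 (chromosome 8, 104601915 to 104624396) was in either list, so the lists hold no value at the targeted gene by which the genotype labels could be checked.

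Among the genes listed for both libraries, Hoxb4, Zfp36l1, Mllt10, Tnrc18 and Ptch1 had the lowest control p-values. In the authors' deposited table the lowest control p-value belonged to Hoxb4, a homeobox regulator of axial patterning (chromosome 11, 96318267 to 96321638), with 1.89e-106 in the control ChIP and 1.93e-14 in the Foxp1KspKO ChIP. The authors' deposited table gave Zfp36l1, which encodes an mRNA decay factor, 3.15e-94 and 2.82e-14, and the chromatin-associated gene Mllt10 2.64e-84 and 4.74e-11. Tnrc18 had 6.50e-66 and 6.37e-09 in the authors' deposited table, and Ptch1, the receptor for hedgehog ligands, had 8.38e-64 and 4.43e-08. Of the 6344 protein-coding control genes, 2900 (45.7%) were also among the 4572 protein-coding Foxp1KspKO genes, leaving 3444 listed for the control ChIP alone and 1672 for the Foxp1KspKO ChIP alone. Random draws of genes from the same chromosomes shared a median of 1339 and at most 1422 genes, a 2.17-fold excess for the observed overlap (one-sided permutation p = 0.001, the smallest that 1000 draws can give).

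The share of control genes that the Foxp1KspKO list also held was larger the stronger the control signal. It was 30.2% (95% interval 28.1 to 32.3) of the 1884 genes with a control p-value from 0.01 to 0.05, 54.6% of the 1069 genes from 1e-06 to 0.0001, and 96.7% (91.8 to 99.1) of the 121 genes under 1e-20. Median −log10 p in the control ChIP was 3.91 for the 3086 shared genes of any biotype and 2.41 for the 3713 genes absent from the Foxp1KspKO list, a difference of 1.5 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Among the shared genes 2203 (71.4%) had the lower p-value in the control ChIP and 883 had it in the Foxp1KspKO ChIP. Across these genes, which are not independent replicates, the −log10 p-values of the libraries correlated with a Spearman rho of 0.27 and a Pearson r of 0.32.

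**Figure D1:**
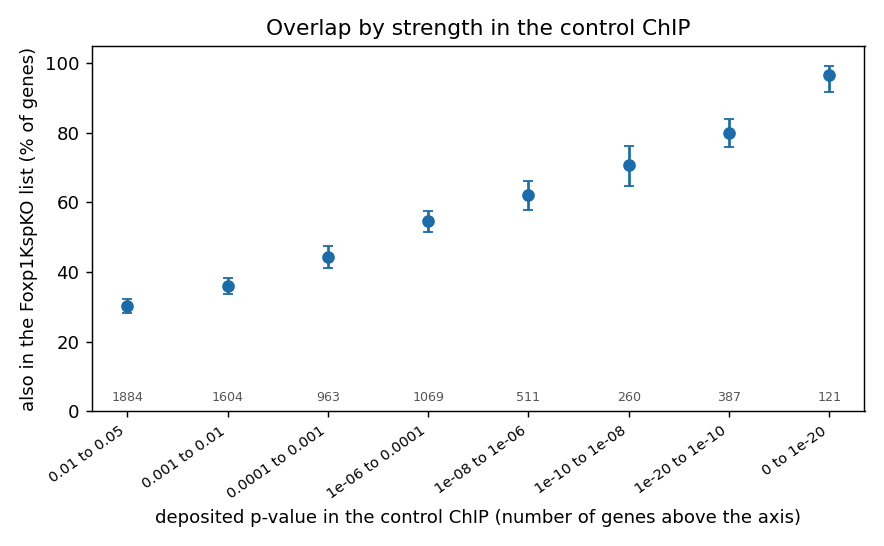
Percentage of control ChIP genes that were also in the Foxp1KspKO list (vertical axis), by the deposited p-value in the control ChIP (horizontal axis, strongest at the right), with exact 95% binomial intervals and the number of genes in each class above the axis. The share is 30.2% in the weakest class and 96.7% in the strongest.

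The 5 lowest p-values of the Foxp1KspKO ChIP belonged to Trim5, Trim30e-ps1, Samt1b, Stfa1 and Zfp997. In the authors' deposited table Trim5 (chromosome 7, 104263386 to 104288254) had 4.67e-44 in the Foxp1KspKO ChIP and 0.00150 in the control ChIP, and Trim30e-ps1, a transcribed pseudogene of the same family on the same chromosome, had 2.85e-34 and 6.02e-07. The authors' deposited table gave Samt1b on chromosome X 7.85e-28 and 5.08e-05, and Stfa1, a stefin gene, 1.93e-26 and 0.0242. Zfp997, a zinc finger gene, had 4.79e-24 in the Foxp1KspKO ChIP and was not in the control list of the authors' deposited table. Whether reads from related genes contribute to these values was not measured here. Of the 57 genes with a Foxp1KspKO p-value under 1e-10, 15 were not in the control list.

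**Figure D2:**
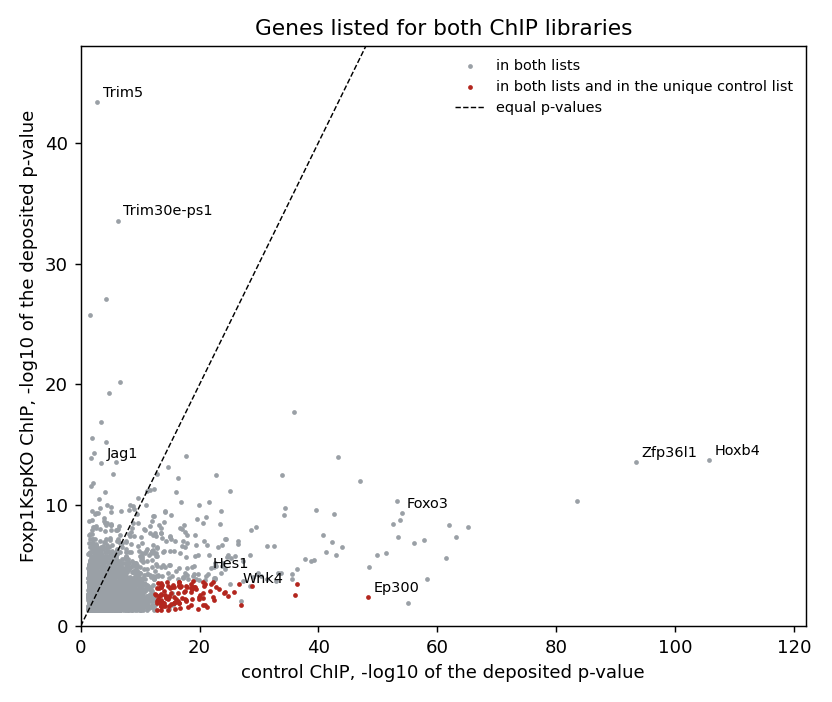
Deposited p-values, as −log10, of the genes listed for both ChIP libraries, with the control ChIP on the horizontal axis and the Foxp1KspKO ChIP on the vertical axis (the axes have different scales); each point is 1 gene, red points are also in the authors' unique control list, and the dashed line marks equal p-values. Hoxb4 and Zfp36l1 lie farthest to the right, Trim5 and Trim30e-ps1 lie highest, and the 116 red points fill a rectangle of strong control and weak Foxp1KspKO p-values; Foxo3 and Jag1 were marked after their values were seen.

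The authors' unique control list held 3483 gene symbols, all present in the control list with unchanged p-values. It was not limited to genes missing from the knockout list, since 116 of its symbols were in both. Those 116 had control p-values of at most 3.35e-13 and Foxp1KspKO p-values of at least 1.93e-04 in the authors' deposited table. Of the 2977 other shared symbols, 9 met both limits and 2968 did not. In the other direction, 336 of the 3703 control symbols absent from the Foxp1KspKO list (9.07%) were not in the unique list.

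Among the 10 unique genes with the lowest p-values, 8 were also in the Foxp1KspKO list. In the authors' deposited table Ep300, the histone acetyltransferase and coactivator p300 (chromosome 15, 81586209 to 81652077), had 3.95e-49 in the control ChIP and 0.00416 in the Foxp1KspKO ChIP. The transcription factor genes Maz and Sp4 followed in the authors' deposited table with 4.72e-37 and 9.44e-37 in the control ChIP and 3.35e-04 and 0.00268 in the Foxp1KspKO ChIP. Tmem164 (2.34e-32) and Phf21a (8.60e-29), a chromatin reader of a corepressor complex, were listed for the control ChIP alone in the authors' deposited table. The other 5 in the authors' deposited table, with control p-values from 1.30e-29 to 1.72e-25, were Ptpn14, a tyrosine phosphatase gene, Jarid2, which encodes a Polycomb cofactor, Zbtb44, Jun, a subunit of AP-1, and Wnk4, a kinase that regulates sodium chloride transport in the distal convoluted tubule (chromosome 11, 101260537 to 101277409).

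Genes of the distal convoluted and connecting tubule and kidney developmental regulators were over-represented in the unique list. The distal list had 8 of 20 members there (40.0%, against 15.1% of all protein-coding genes; odds ratio 3.76, 95% interval 1.33 to 10.0; Fisher's exact test, adjusted p = 0.0457). Its strongest members in the authors' deposited table were Wnk4 (1.72e-25), the potassium channel gene Kcnj16 (2.38e-05) and Stk39 (4.67e-05), whose kinase SPAK acts downstream of the WNK kinases. Another 8 members were in neither the control nor the Foxp1KspKO list, among them Slc12a3, Pvalb and Calb1, named after their values were seen. The developmental list had 11 of 30 members (36.7%; odds ratio 3.27, 1.40 to 7.23; adjusted p = 0.0457), among them Hoxd11 (2.34e-17) and Etv5 (2.08e-14) in the authors' deposited table. Wnk4 was also in the Foxp1KspKO list, with 0.00319 in the authors' deposited table, and Hoxd11 and Etv5 were also in the Foxp1KspKO list, with 0.0126 and 3.80e-04 in the authors' deposited table. Against 10000 random lists matched on gene length the excess was of similar size, 2.34-fold for the distal list (2.65-fold over all genes) and 2.51-fold for the developmental list (2.43-fold). Neither passed there (two-sided permutation p = 0.0244 and 0.00520, adjusted p = 0.183 and 0.0780), although both counts lay above the central 95% of the random lists, 1 to 7 and 1 to 8 genes. When only control genes absent from the Foxp1KspKO list were counted, the distal list had 7 members (odds ratio 2.89, 0.975 to 7.80; Fisher's exact test, adjusted p = 0.417) and the developmental list 8 (odds ratio 1.95, 0.750 to 4.55; adjusted p = 0.472).

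The intercalated cell list, which covers the acid-base transporting cells of the collecting duct and their regulators, had 6 of 25 members in the unique list (24.0%; odds ratio 1.78, 0.581 to 4.64; adjusted p = 0.570) and did not pass. In the authors' deposited table these were the homeobox gene Hmx2 (1.88e-13), the anion exchanger gene Slc26a7 (2.57e-08), the proton pump subunit gene Atp6v1c2 (5.82e-06), the alkali-sensing receptor gene Insrr (0.00727), Dmrt2 (0.0309) and Slc26a4 (0.0435), which encodes pendrin. None of the 6 was in the Foxp1KspKO list, but neither were 3367 of the 3483 unique symbols, so this absence is not particular to them. Foxi1, the regulator of intercalated cell identity (chosen after the values were seen), was in neither list. V-ATPase subunits had 3 of 25 members (12%; odds ratio 0.768, 0.147 to 2.56; adjusted p = 1.00), Atp6v0a1 (4.25e-06), Atp6v1c2 and Atp6v0d1 (0.00461) in the authors' deposited table.

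Notch pathway genes had 8 of 30 members in the unique list (26.7%; odds ratio 2.05, 0.789 to 4.79; adjusted p = 0.355), which did not pass. They included the effector genes Hes1 (8.51e-25), Hey2 (2.04e-08), Hey1 (4.29e-07) and Heyl (1.62e-05) and the DNA-binding partner of Notch, Rbpj (1.94e-19), in the authors' deposited table, besides Mib1 (0.00133), Adam10 (0.00541) and Lfng (0.00770). Hes1 and Rbpj were also listed for the Foxp1KspKO ChIP, with 0.00172 and 0.00608 in the authors' deposited table. The ligand gene Jag1, chosen after its values were seen, had 3.15e-14 in the Foxp1KspKO ChIP and 3.27e-04 in the control ChIP of the authors' deposited table. The forkhead family had 8 of 39 members in the unique list (20.5%; odds ratio 1.45, 0.577 to 3.24; adjusted p = 0.611). These were, in the authors' deposited table, Foxd3 (2.46e-19), Foxl1 (1.25e-10), Foxd4 (1.61e-07), Foxn2 (2.51e-07), Foxp4 (2.76e-04), Foxb1 (0.00300), Foxq1 (0.00520) and Foxc2 (0.0413), and Foxd3 had 3.13e-04 in the Foxp1KspKO ChIP as well.

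The remaining lists did not pass in the unique list. The Wnt list had 9 of 30 members (adjusted p = 0.180), led by Lef1, Tcf7l2 and Fzd4, and the cell cycle list 6 of 26 (adjusted p = 0.570), led by the inhibitor gene Cdkn2c, Rb1 and E2f3. Lef1, Tcf7l2, Fzd4 and Cdkn2c were also in the Foxp1KspKO list, with 2.38e-04, 2.26e-04, 5.51e-04 and 5.60e-04 in the authors' deposited table. Rb1 and E2f3 were not. The principal cell list had 2 of 18, Nedd4l and Gata2 (adjusted p = 1.00), and the thick ascending limb list 3 of 16, Irx2, Irx1 and Slc12a1, the target of loop diuretics (adjusted p = 0.904). Among other cell types, podocytes had 3 of 16 members, Tcf21, Lmx1b and Foxc2 (adjusted p = 0.904), endothelium 2 of 16, Sox17 and Flt1 (adjusted p = 1.00), and stromal and immune cells 1 of 18, Meis1 (adjusted p = 0.756). Ribosomal protein genes had 2 of 30, Rps29 and Rps23 (adjusted p = 0.570), and proximal tubule genes 0 of 21 (adjusted p = 0.231).

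Both whole lists were rich in kidney developmental, Wnt, forkhead and cell cycle genes; the tests of the whole control list, and those of both lists against length-matched lists, were chosen after the data were seen. The control list held 22 of the 30 kidney developmental regulators (73.3%; odds ratio 6.76, 2.90 to 17.6; adjusted p = 9.41e-06) and the Foxp1KspKO list 14 (46.7%; odds ratio 3.32, 1.5 to 7.27; adjusted p = 0.0171). Wnt pathway genes numbered 17 and 14 of 30 (adjusted p = 0.00690 and 0.0171), forkhead genes 20 and 16 of 39 (adjusted p = 0.0119 and 0.0212), and cell cycle genes 17 and 12 of 26 (adjusted p = 9.47e-04 and 0.0212). These calls passed against random lists matched on gene length, with adjusted p-values from 0.00300 to 0.0225. Proximal tubule genes were under-represented in the control list, with 0 of 21 (0%, interval 0 to 16.1; adjusted p = 0.00567), and the Foxp1KspKO list had 1 of 21, the fatty acid transporter gene Slc27a2, named after its value was seen (adjusted p = 0.218). Ribosomal protein genes numbered 10 of 30 in the control list (adjusted p = 0.937) and 12 of 30 in the Foxp1KspKO list (adjusted p = 0.0636, or 0.0300 against lists matched on gene length).

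None of the 15 fixed lists passed the test of a difference between the libraries. Of the kidney developmental regulators, 8 were in the control list alone, 0 in the Foxp1KspKO list alone and 14 in both (Fisher's exact test on genes in 1 list only, p = 0.0597, adjusted p = 0.421). For the distal convoluted and connecting tubule the numbers were 7, 1 and 4 (odds ratio 3.40, 0.437 to 153; adjusted p = 0.747), for the Notch pathway 6, 1 and 7 (2.92, 0.353 to 134; adjusted p = 0.877), and for intercalated cells 7, 3 and 1 (1.13, 0.258 to 6.8; adjusted p = 1.00). These intervals are wide and include 1. Adjusted over the list alone, 22 developmental, 10 distal, 13 Notch and 5 intercalated cell genes passed in the control list, and 19, 8, 13 and 5 passed when adjusted over all protein-coding genes. In the Foxp1KspKO list 12, 4, 7 and 3 passed when adjusted over the list alone, and 11, 4, 4 and 3 over all protein-coding genes.

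**Figure D3:**
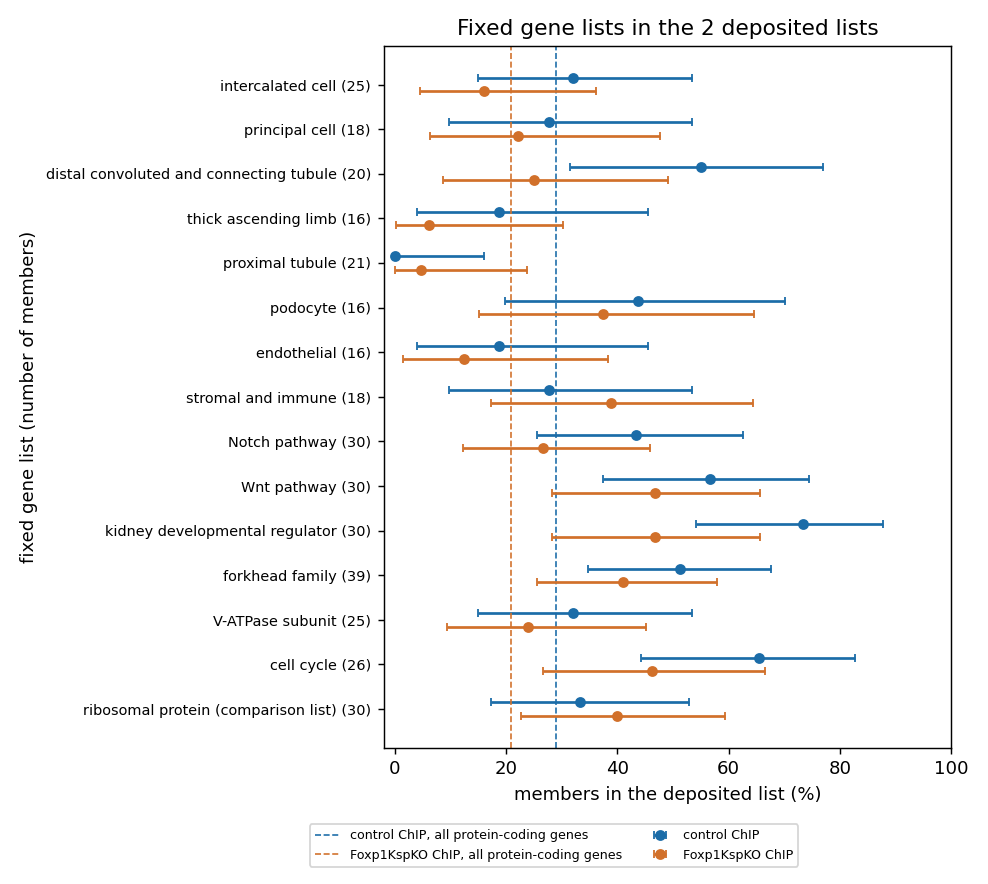
Percentage of each fixed gene list (vertical axis, number of members in brackets) found in the deposited list of the control ChIP (blue) and of the Foxp1KspKO ChIP (orange), with exact 95% binomial intervals; dashed lines mark the share of all protein-coding genes, 29.0% and 20.9%. Kidney developmental regulators lie at 73.3% and 46.7%, and proximal tubule genes at 0% and 4.76%.

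Listed genes were longer than the rest, with a median of 23814 bp against 15237 bp for the control ChIP and 20713 bp against 16406 bp for the Foxp1KspKO ChIP. They were also unevenly spread over the chromosomes. In the control list 39.1% of the 966 X-linked and 28.7% of the 20665 autosomal protein-coding genes were present (odds ratio 1.60, 1.40 to 1.83; Fisher's exact test, p = 1.05e-11). In the Foxp1KspKO list the shares were 21.7% and 21.0% (odds ratio 1.04, 0.889 to 1.22; Fisher's exact test, p = 0.600). Single autosomes ranged from 22.2% to 39.7% in the control list, and chromosome 18 was at the upper end.

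**Figure D4:**
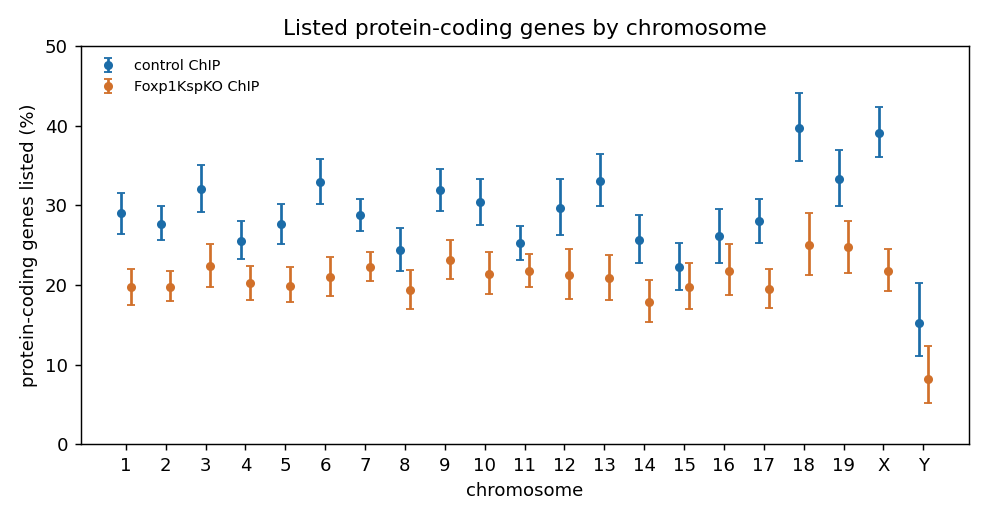
Percentage of the protein-coding genes of each chromosome (horizontal axis) found in the deposited list of the control ChIP (blue) and of the Foxp1KspKO ChIP (orange), with exact 95% binomial intervals. Chromosomes 18 and X have the highest shares in the control ChIP, 39.7% and 39.1%, and chromosome Y the lowest, 15.2%.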

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

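The tests of gene families and gene length were set before their results were seen, and the comparisons of X with autosomes between the libraries, across chromosomes and by symbol family were chosen afterwards. The X chromosome set the libraries apart: among genes present in only 1 of the 2 lists, 231 X-linked genes were in the control list and 63 in the Foxp1KspKO list, an odds ratio of 1.84 against autosomal genes (1.38 to 2.49; Fisher's exact test, adjusted p = 1.98e-04 over 16 comparisons). The tables argue against multi-copy families as the whole cause, since outside symbol families of 10 or more members the odds ratio of X against autosomes in the control list was 1.63 (1.35 to 1.98). They argue against gene length as well, with 1.67 (1.46 to 1.91) within length deciles. Genes of 1 chromosome are not independent, and by chromosome the ratio of the control share to the Foxp1KspKO share was 1.80 for X against 1.12 to 1.59 for the 19 autosomes and 1.86 for Y (one-sided exact p = 0.05 for X among the autosomes, the smallest this comparison can give). The genotype, the sex of the animals behind each ChIP and input, and base composition stay open as untested explanations.

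Receptor genes of the vomeronasal organ and the olfactory epithelium also differed between the deposited lists. Vomeronasal receptor genes (symbols Vmn) numbered 115 in the control list alone and 13 in the Foxp1KspKO list alone (odds ratio 4.41, 2.47 to 8.55; adjusted p = 2.80e-07 over 111 symbol families). Olfactory receptor genes (Olfr) numbered 260 and 70 (odds ratio 1.87, 1.42 to 2.49; adjusted p = 1.47e-04). Members of these families share sequence, so short reads can be divided among them. This applies to both libraries and was not measured, so the cause of the difference stays open. Related genes are also not independent, which the test does not take into account.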

How the results depend on the processing

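The alternatives that leave out symbol families, limit the strength difference to autosomes, match overlap draws on gene length, adjust over all genes, use the whole control list or drop unique genes also listed for Foxp1KspKO were chosen after the data were seen. The overlap stayed above random draws (2.09 to 2.76-fold) and the strength difference stayed positive (1.51 and 1.77) in the alternatives run. The gene numbers, of any biotype, were 3401 control and 1636 Foxp1KspKO genes at or below the control median p-value. Of the 6344 and 4572 protein-coding genes, 3414 and 2534 remained without families of 10 or more members. When adjusted over all protein-coding genes, 4668 and 2256 passed. Fewer genes enter by construction. The number of fixed lists passing, 2 in the unique list, was 0 for control genes absent from the Foxp1KspKO list by identifier, 0 for unique genes absent from it, 0 against length-matched lists (where the excess was 2.34-fold for distal and 2.51-fold for developmental genes, beside 2.65 and 2.43 unmatched, and p doubles the smaller tail), 4 in the Foxp1KspKO list and 5 in the whole control list. Among unique genes with stronger p-values (at or below their median) it was 2, developmental regulators and Wnt. The distal list did not pass there (Fisher's exact test, adjusted p = 0.0744), though its odds ratio was 4.06 (1.15 to 11.8), beside 3.76 in the unique list. Among unique genes absent from the Foxp1KspKO list the odds ratios were 3.16 (distal) and 2.14 (developmental), beside 3.76 and 3.27. For Wnt the odds ratio was 1.17 there, beside 2.42 in the unique list and 4.44 among the stronger unique genes. Odds ratios crossed 1 in the Foxp1KspKO list for intercalated cells (0.722), principal cells (1.08), thick ascending limb (0.253), stromal and immune cells (2.41), V-ATPase (1.2) and ribosomal genes (2.53). They did so among the stronger unique genes for principal cells (1.52), thick ascending limb (0.811), podocytes (0.811) and V-ATPase (1.06), and in the whole control list for thick ascending limb (0.566), V-ATPase (1.15) and ribosomal genes (1.23); the cause was not tested. The fixed lists and alternatives together gave 90 values. Of these, 60 kept direction and side of the threshold, 13 crossed 1, 9 lost and 8 gained the call. All 9 losses fell on the 2 lists that passed in the unique list. The distal list lost its call in every alternative, including the whole control list (Fisher's exact test, adjusted p = 0.0570). The developmental list kept its call among the stronger unique genes, in the whole control list and in the Foxp1KspKO list from the other library. The other kept values belong to lists that did not pass before or after the change. Alternatives that need peak positions or sequence (merging, overlap share, centre distance, another strength measure, promoter and distance limits, motif) were not run. No paired analysis was possible because each group holds 1 library. Depth is unknown and could not be weighed.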

Other observations

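The tests of the IgG label, newer symbols, a p-value limit and symbol families, and the counts of strong Foxp1KspKO genes absent from the control list or outside symbol families, were chosen after the results were seen. Genes that share a symbol stem fell unevenly into the control list. Vomeronasal receptors had 185 of 355 members there (52.1%; Fisher's exact test, adjusted p = 4.88e-18 over 111 families), and olfactory receptors 381 of 1110 (34.3%; adjusted p = 0.00194). The Btbd genes (28 of 42, 66.7%), the zinc finger genes named Zfp (159 of 397, 40.1%), the Tbc genes (18 of 30, 60.0%) and the Zbtb transcription factor genes (21 of 41, 51.2%) were also over-represented, with adjusted p from 2.53e-05 to 0.0295. A stem groups genes by name alone, and the Btbd stem includes numbered copies such as Btbd35f19, many of them in the control list. Solute carriers were under-represented, with 80 of 375 (21.3%; adjusted p = 0.0134), as were Cd (14 of 100), keratin (5 of 53), Tex (3 of 39), Prss (3 of 39), Ly (1 of 25) and Lrrc genes (9 of 67). In the Foxp1KspKO list 0 of the 111 families passed Fisher's exact test after adjustment, and 10 had an unadjusted p under 0.05. By itself this does not set the lists apart. Zbtb genes had odds ratios of 2.58 in the control list and 2.69 in the Foxp1KspKO list (Fisher's exact test, unadjusted p = 0.00292 and 0.00302). Between the libraries only 2 families passed, the vomeronasal and olfactory receptors, while Btbd and Zfp genes had adjusted p = 0.448 and 0.475 (Fisher's exact test on genes in 1 list only).

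The control list was the longer and stronger of the pair. Of the 57 Foxp1KspKO genes with p under 1e-10, 36.8% (24.4 to 50.7) had a control p-value as low or lower, and 26.3% (15.5 to 39.7) were not in the control list. For the 25 protein-coding genes outside symbol families of 10 or more members these shares were 40.0% (21.1 to 61.3) and 16.0% (4.54 to 36.1). Greater depth alone was predicted, before the result was seen, to give a share above both intervals of the first share. Both intervals nevertheless reach past the lower limit that was set to count against that explanation. The genes were picked by low Foxp1KspKO p-values from 1 library, so depth stays open, as does the genotype, which was not tested. The label's rabbit IgG for the control ChIP cannot be told apart from a Foxp1 antibody by the 2.17-fold overlap, since a background shared by both libraries would also give an overlap.

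The unique list lacked 336 control symbols that the Foxp1KspKO list did not hold. A candidate explanation is a step that matched symbols against an older annotation: 18 of the 336 symbols, against 5 of the 3483 unique ones, were not current in the RefSeq table (odds ratio 39.3, 13.9 to 136; Fisher's exact test, p = 1.45e-15). The remaining symbols were current in the RefSeq table, but a current symbol can still be newer than an older annotation. That annotation is unknown, so the part of the 336 that this step accounts for cannot be given. A p-value limit is argued against, since 42.6% (37.2 to 48) of the missing genes had a p-value under the median of the unique list. No biological explanation was tested.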
